A study of Mus musculus with 12 samples.

How the data were processed

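The authors, per the submitters' processing notes, checked reads with FastQC, trimmed them with Trimmomatic, aligned them with STAR to the mouse genome build mm10 (GRCm38), counted reads in genes with featureCounts and normalized the counts with DESeq2. The versions and settings of these tools are not given in the sources used here. Per the sample descriptions, tumours were digested with collagenase IV and DNase, RNA was extracted with Trizol, libraries were made with the SMARTer Stranded Total RNA-Seq v2 Pico Input kit, and 100-base paired reads were sequenced on a NovaSeq. The deposited signal values are DESeq2-normalized counts, which the authors made by dividing read counts by a size factor per sample, in 1 file of 55401 gene identifiers and 12 columns. Multiplying each column by its recovered factor gave whole reads within 0.001 in 100% of values, with a largest deviation of 1.4e-08. Symbols and coordinates from the GENCODE vM21 annotation were matched to 55141 identifiers (99.53%), and 6975 genes were at 0 in all libraries. The gene with most reads in a library, the predicted gene Gm23935 or the mitochondrial ribosomal gene mt-Rnr2, took 6.58% to 13.62% of reads.

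The comparisons, gene lists, tests and rule for naming genes were written down before the data were examined. Genes with a normalized count of at least 10 in at least 3 libraries were tested, 18274 in all. Log2 of the deposited normalized count plus 1 was fitted with limma, all 12 samples in 4 groups, with the variance trend on, 8 residual degrees of freedom and 3.313 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. A gene was said to rise or fall only past that threshold. The ± after a log2 fold change is the SE of the fit, and the ± after a mean is the SD with n = 3.

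The replicate number was fitted as a block in an alternative, with 6 residual degrees of freedom. The labels do not say what the number stands for. Residuals of samples with the same number correlated at 0.473 to 0.621 (fusion protein), 0.156 to 0.496 (20 Gy) and 0.334 to 0.389 (combined) against untreated. For combined against fusion protein this was 0.41 to 0.484. The 0.156 was for number 2, where another number correlated more. Blocked values are given for these comparisons where they change a call. For combined against 20 Gy the range was 0.01 to 0.505, so the block is not given there.

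Gene lists, 37 with 686 genes, were fixed before the data were examined and tested with camera at its preset correlation of 0.01 and with an estimated correlation, and by fry. Camera called 95 of 216 list tests, 21, 15, 14, 17, 19 and 9 in the order of the comparisons. With an estimated correlation 2 held, the type I interferon list with the fusion protein alone and when added to 20 Gy, and fry called 3. The keratinocyte list had 4 measured members and was not tested, with medians of −0.26 after 20 Gy and 0.23 with the fusion protein. The median, mean and camera direction of a list differed in sign only in lists that camera did not call, such as coinhibition with the fusion protein (median −0.16, mean 0.07). The mature regulatory dendritic cell list shares 16 of its 34 genes with other lists, IL-4 and STAT6 12 of 17, interferon gamma 11 of 30, macrophage 10 of 26, cDC1 5 of 18, neutrophil 2 of 17 and type I interferon 2 of 38, while T cell, erythroid and melanoma share 0. Untreated means reached 10 in 13 of 17 neutrophil, 8 of 8 erythroid, 22 of 24 macrophage and 12 of 15 melanoma genes tested. Library 1 was highest for the first 2.

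Named genes were Ccl22, Ccl17, Ccr7, Fscn1, Cd274, Il12b, Cxcl9, Cxcl10, Foxp3 and Itgax in every comparison. In each comparison the 8 largest rises and 8 largest falls past the threshold were named too, if all 3 values of one group lay outside the range of the other and the higher mean was at least 50. Predicted genes and immunoglobulin or T cell receptor segments were left out. Where fewer than 4 passed, the 6 higher and 6 lower genes of smallest p were named as not passing. Of each list described, up to 4 members of smallest p were named. Markers and list members named beyond these were chosen after their values were seen, as were the receptor genes and Tyrp1. Genes of near-identical sequence may share reads, so values within the Ifit3 and Ifit3b, Cd209, Hba-a1 and Hba-a2, H2-Q, Oas, Gbp, Sh2d1b and Xlr3 families are uncertain.

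On simulated counts with known changes, the same steps recovered 5 of 67 genes changed by a log2 of 1, 30 of 67 changed by 2 and 49 of 66 changed by 3 in the fusion protein comparison, with 1 false call among 17222 unchanged genes. For 20 Gy they recovered 2 of 67, 28 of 67 and 48 of 65, with 2 false calls among 17220. The changed list was called in both and 0 of 36 unchanged lists were, with correlation within lists not tested. A log2 fold change near 1 was therefore seldom detectable at this depth and spread. The median chi-square per gene within groups was 3.28 for 20 Gy libraries 1 and 2 and 12.4 to 53.3 for other pairs. Repeat sequencing of 1 library gives 0.455.

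Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.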

Results

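Living cells that carry CD45, a surface protein of white blood cells, and CD11c, an integrin chain of dendritic cells and many macrophages, were sorted from B16-OVA tumours. B16-OVA is a mouse melanoma line that carries the chicken ovalbumin gene as a model antigen. Tumours had grown for 10 days when the mice received 20 Gy of radiation, a fusion protein, both treatments or neither. The dose of the fusion protein was 20 mcg at first, on the day of radiation, and 10 mcg on day 14. Cells were collected on day 17. The parts of the fusion protein are not given in the sources used here, so it is described only by that name. RNA of the sorted cells was sequenced from 12 libraries, 3 in each of 4 groups, called here untreated, fusion protein, 20 Gy and combined. The series is about a dendritic cell program of the chemokine CCL22 and resistance to radiation, so Ccl22 and 9 other genes of interest are given in every comparison. The labels do not say that samples of a group came from separate mice, so p-values measure the spread between these samples, which may be partly technical.

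Library depth was 14462032 to 23985496 reads in genes, and 22100 to 43326 genes had a read in each library. Of 1754 olfactory, vomeronasal and trace-amine receptor genes, which are silent in immune cells, 78.96% had a read in library 1 and 59.01% in library 2 of the 20 Gy group, and 13.11% in library 3. In the combined group these shares were 57.7%, 13.63% and 39.68%. In the untreated and fusion protein groups they lay between 4.79% and 25.48%. The share of reads from mitochondrial genes was 18.57% in library 3 of the 20 Gy group and 6.95% to 14.34% in the others. Transcripts of melanoma cells were highest in the libraries numbered 3: Tyrp1, a pigment enzyme of melanocytes, had 464.5 normalized counts in untreated library 3, 1147 in fusion protein library 3, 4718.1 in 20 Gy library 3 and 202.8 in combined library 3, against at most 38.5 in the other 8. The mean log2 level of the B and plasma cell list was 5.41, 6.13 and 5.97 in library 3 of the untreated, fusion protein and 20 Gy groups, and 9.19 to 10.32 in the other 6 libraries of these groups. These facts bear on each group of genes described, in every comparison.

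**Figure D1:**
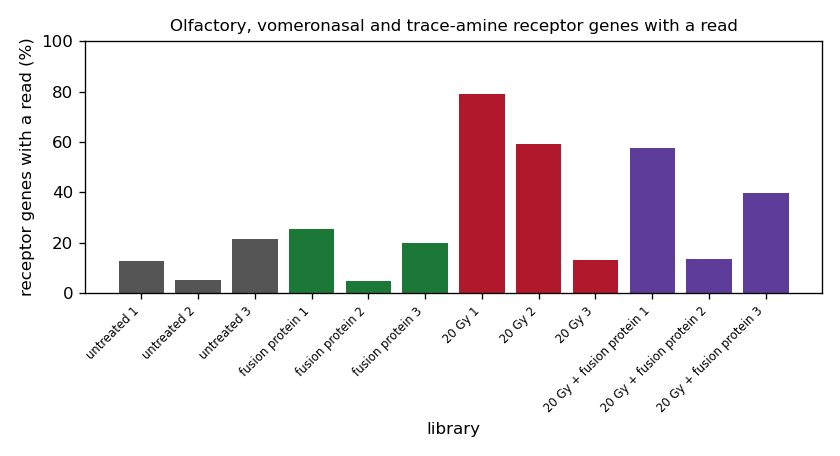
Share of 1754 olfactory, vomeronasal and trace-amine receptor genes with at least 1 read (y axis, percent) in each of the 12 libraries (x axis), with bars coloured by group. The 3 highest bars are 20 Gy library 1 (78.96%), 20 Gy library 2 (59.01%) and combined library 1 (57.7%).

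The first comparison asked what 20 Gy alone did to the sorted cells by day 17. By camera, lists of neutrophil, red cell and macrophage transcripts ranked higher after 20 Gy and lists of T cell and cytotoxic transcripts lower, with no single gene past the threshold over all genes. None of these calls held with an estimated correlation (adjusted p 0.351 to 0.579). S100a8, a calcium-binding protein that neutrophils make in bulk, averaged 570.6 ± 141 normalized counts (SD, n = 3) after 20 Gy and 79.3 ± 133.7 without treatment. Hba-a1, an alpha globin of red cells (chromosome 11, 32283511 to 32284465), averaged 556.6 ± 257 and 49.4 ± 83.7. Hp, which encodes the haemoglobin-binding haptoglobin, averaged 420.4 ± 117 and 80.1 ± 68.9, and C3, the central complement component, 1532 ± 456 and 663 ± 151. Lck, a kinase of the T cell receptor pathway, averaged 1430 ± 398 after 20 Gy and 3071 ± 1606 without.

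All 17 neutrophil members were higher after 20 Gy (median log2 fold change 2.86), 0 passing over all genes and 11 over the list alone. With the replicate number as a block, 2 passed, S100a8 (limma, adjusted p = 0.0475) and the siderophore-binding Lcn2 (log2 5.81, adjusted p = 0.0488). All 8 erythroid members were higher (median 4.73) and passed when adjusted over the list alone, with 0 over all genes. Camera gave the 2 lists adjusted p values of 9.5e-13 and 1.1e-07, and 0.351 and 0.374 with an estimated correlation. In untreated libraries, in number order, log2 means were 6.4, 2.6 and 3.6 (neutrophil) and 6.6, 0.8 and 2.7 (erythroid). After 20 Gy they were 7.2 to 8.3, nearest to untreated library 1. All 24 macrophage members were higher by a median of 1.58, among them C1qc at 1.66 and C1qa at 1.32, which form the C1q complement protein, and 0 passed either way. For this list camera gave an adjusted p of 3.9e-08, and 0.351 with an estimated correlation. Of 16 monocyte members 14 were higher (median 1.19), and Hp at 2.72 and Chil3 at 2.98, a chitinase-like secreted protein, passed when adjusted over the list alone. With the block 4 of the 16 passed, and 1 of the 8 erythroid members. Camera gave an adjusted p of 0.00019 for the monocyte list, and 0.384 with an estimated correlation. The cDC1 list, markers of the conventional dendritic cells that cross-present antigen, was higher in 16 of 18 members, by a median of 0.80, with 0 passing. Cadm1, an adhesion molecule of cDC1, had a log2 fold change of 1.06 ± 0.33 (SE) and Tlr3, a receptor for double-stranded RNA, of 1.42 ± 0.45, and Tlr3 passed with the block (limma adjusted p = 0.0454). Camera gave the cDC1 list an adjusted p of 3.1e-05, and 0.351 with an estimated correlation.

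Lower after 20 Gy were all 23 T cell members (median −0.88, with Lck among them), 19 of 20 cytotoxic and NK cell members (median −0.69) and 15 of 16 plasmacytoid dendritic cell members (median −0.61), with 0 passing over all genes or over the list alone. Camera gave adjusted p values of 1.1e-07, 2.7e-07 and 2.2e-05. These became 0.579, 0.384 and 0.384 with an estimated correlation. The camera calls of the neutrophil, erythroid, macrophage, monocyte, cDC1, T cell, cytotoxic and plasmacytoid lists were kept in each of the 6 fits that left out 1 library. The lipid handling list was also kept (median 1.04, camera adjusted p = 0.00067, adjusted p = 0.351 with an estimated correlation).

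Several programs were called by camera after 20 Gy only while library 3 of that group was in the fit. The type I interferon list had 34 of 38 members higher, by a median of 0.43 (camera adjusted p = 2.2e-05), and an adjusted p of 0.555 without 20 Gy library 3. The same held for chemokines (median 1.19, adjusted p 0.0293, and 0.504 without it), cytokines (0.66, 0.0125 and 0.761), coinhibition and immunoregulation (0.40, 0.0158 and 0.901), cell cycle (0.35, 0.00166 and 0.418), lysosome and complement (0.58, 9.4e-06 and 0.141), melanoma (1.98, 0.00484 and 0.909), fibroblast and endothelium (2.36, 0.00174 and 0.195) and mitochondrial transcripts (0.44, 0.00724 and 0.974). Leaving out untreated library 1 also ended the calls of chemokines, cytokines, coinhibition, cell cycle, melanoma, fibroblast and mitochondrial lists, and leaving out untreated library 2 those of chemokines and cytokines. MHC class I presentation was lower (median −0.12, camera adjusted p = 0.0385, and 0.87 without untreated library 3, with the call also lost without 20 Gy library 1 or 2). MHC class II presentation (0.40, 0.0317) had an adjusted p of 0.259 without untreated library 2, and innate sensing (0.60, 0.03) of 0.278. Both were lost without 20 Gy library 3 too, and MHC class II without untreated library 3. With an estimated correlation the adjusted p was 0.714 for the type I interferon list, 0.719 for chemokines, cytokines, cell cycle, MHC class II, melanoma and mitochondrial transcripts, 0.579 for coinhibition, 0.508 for lysosome and complement, 0.384 for fibroblast and endothelium, 0.824 for MHC class I and 0.681 for innate sensing. Without 20 Gy library 3 the median was 1.31 for fibroblast and endothelium, 0.26 for lysosome and complement, 0.21 for cell cycle, 0.19 for the type I interferon list, 0.12 for cytokines, 0.11 for coinhibition, 0.06 for melanoma, 0.05 for mitochondrial transcripts and −0.07 for chemokines.

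The p53 response list, targets of the DNA damage pathway, had a median of 0.14 and 15 of 24 members higher (camera adjusted p = 0.904). Its members of smallest p were Phlda3 (1.10) and Bax (0.46). Glycolysis and hypoxia had a median of 0.34 (camera adjusted p = 0.313, 0.0115 with the block, and 0.752 with the block and an estimated correlation). The mature regulatory dendritic cell list, which holds Ccl22, Ccr7 and Fscn1, had a median of 0.20 (adjusted p = 0.612). Of the dissociation stress list, Hspa1a and Hspa1b, heat shock chaperones, passed when adjusted over the list alone (log2 1.80 and 1.86), with a list median of −0.16 and an adjusted p of 0.522. Costimulation (0.60), NF-kB response (0.09), cholesterol synthesis (0.04), TGF-beta response (0.27), IL-4 and STAT6 response (0.29), interferon gamma response (−0.05), cDC2 (0.24), pan conventional DC (0.19), regulatory T cell (−0.11), B and plasma cell (−0.05), and mast cell and basophil (1.12) had camera adjusted p values of 0.313 to 0.985.

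**Figure D2:**
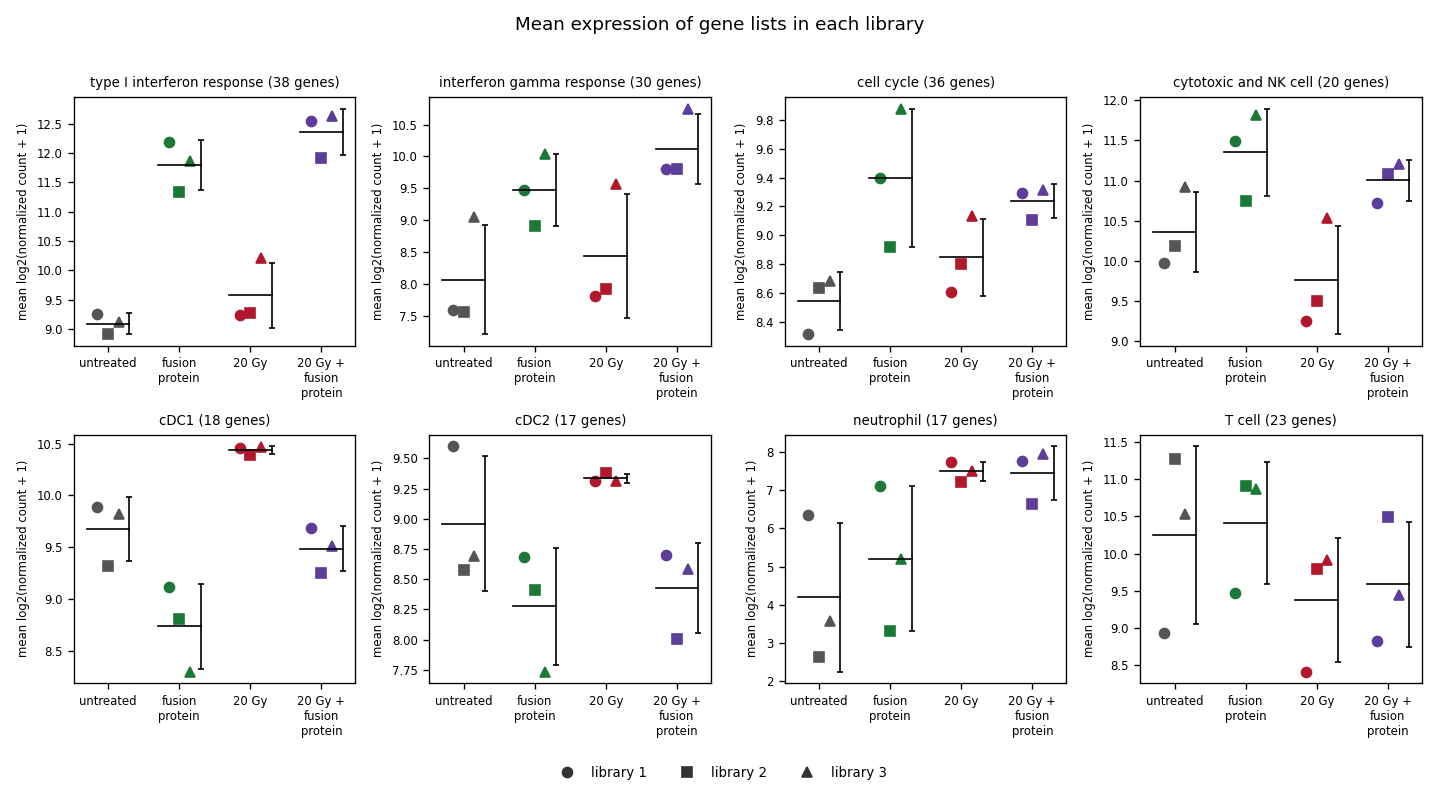
Mean of log2(normalized count + 1) over the members of each of several gene lists (y axis) in the 3 libraries of each group (x axis), with points for libraries and the group mean ± SD. The type I interferon list lies at 8.91 to 10.21 in the 6 libraries without the fusion protein and at 11.34 to 12.64 in the 6 with it.

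Ccl22, a chemokine that attracts CCR4-bearing regulatory T cells (ENSMUSG00000031779.3, GRCm38 chromosome 8, 94745590 to 94751699), averaged 1377 ± 2058 normalized counts after 20 Gy and 399.2 ± 268 without treatment (SD, n = 3). Its 20 Gy values were 105, 274 and 3751, so the mean rests on library 3. The log2 fold change was 0.56 ± 1.44 (SE; limma adjusted p = 0.957). The other genes fixed for every comparison spread in the same way. Ccr7, the receptor that guides mature dendritic cells to lymph nodes, had 390, 682 and 6545 counts after 20 Gy, and Fscn1, an actin-bundling protein of mature dendritic cells, had 454, 955 and 6832. Log2 fold changes were 1.72 for Ccl17, −0.47 for Ccr7, 0.05 for Fscn1, 0.37 for Cd274, which encodes the checkpoint ligand PD-L1, and 0.99 for Il12b, a subunit of IL-12. They were 0.38 for Cxcl9 and 0.56 for Cxcl10, chemokines that attract T cells, 0.33 for Foxp3, the transcription factor of regulatory T cells, and 0.06 for Itgax, which encodes CD11c. The limma adjusted p of these 9 genes lay between 0.812 and 0.995.

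**Figure D3:**
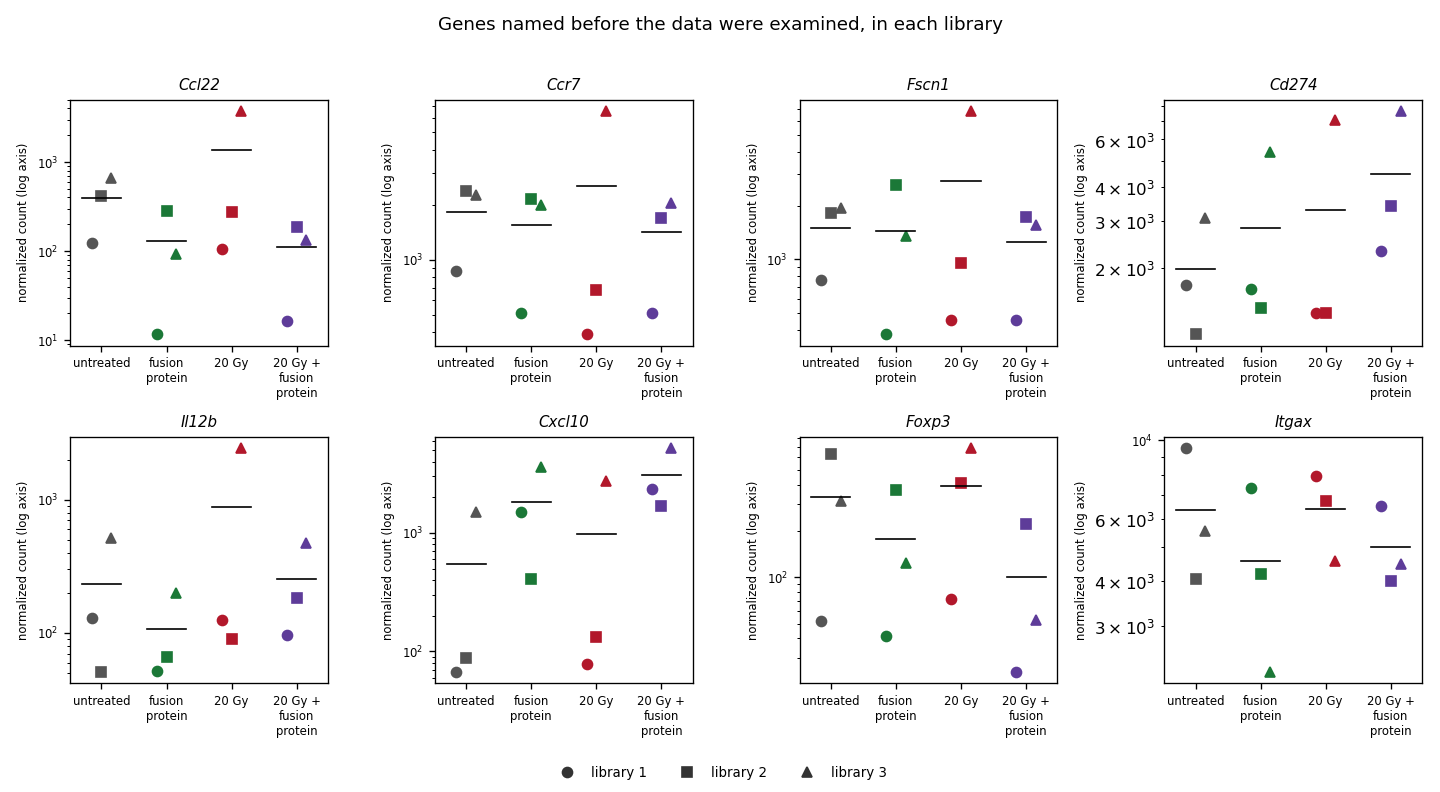
Normalized counts (y axis, log scale) of Ccl22, Ccr7, Fscn1, Cd274, Il12b, Cxcl10, Foxp3 and Itgax in the 3 libraries of each group (x axis), with a line at the group mean. Ccl22 after 20 Gy is at 105, 274 and 3751.

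Over 18274 genes, limma called 0 between 20 Gy and untreated samples, against 1231 at an unadjusted p under 0.05. The quasi-likelihood test of edgeR called 0, DESeq2 called 45 (41 higher), and limma with the replicate number as a block called 70 (57 higher). The 6 higher genes of smallest p all had a limma adjusted p of 0.282. Among them Col4a4, a basement membrane collagen chain, averaged 33.5 ± 9.23 counts after 20 Gy and 0.25 ± 0.43 without, Srgap1, a protein of the Slit and Robo pathway, 47.3 ± 28.3 and 1.17 ± 1.13, and Xlr3b, an X-linked lymphocyte-regulated gene, 28 ± 2.73 and 0.915 ± 0.802 (SD, n = 3). Eya4 averaged 27.5 ± 10.7 and 0.594 ± 0.534. Syt14 (15.3 ± 4.4) and Dpyd (17.2 ± 3.6) were at 0 in all untreated libraries. With the block the adjusted p was 0.0438 for Col4a4, Srgap1 and Xlr3b, 0.0475 for Syt14 and Eya4 and 0.0518 for Dpyd. With the receptor gene level as a covariate, chosen post hoc, none passed. Log2 fold changes were 4.06 (Xlr3b, 4.02 without it), 4.73 (Srgap1, 4.49), 3.94 (Col4a4, 4.80), 3.51 (Eya4, 4.16), 3.73 (Syt14) and 3.63 (Dpyd). Ccl22 went to 2.85, Ccr7 to 1.09, Fscn1 to 1.73, Foxp3 to 2.03, Cxcl10 to 0.36 and Itgax to −0.18. The 6 lower genes of smallest p were Adamts14, a collagen-processing protease (1122 ± 111 against 2129 ± 366; limma adjusted p = 0.442, and 0.0481 with the block), Nlrc3, an intracellular inhibitor of immune signalling (694 ± 68.1 against 1455 ± 438; 0.477 and 0.0481), Cuedc1 (190.6 ± 21.7 against 395 ± 134), Plekhf1 (log2 −1.25), Unkl (−0.70) and Il18rap, a chain of the IL-18 receptor (−0.80). No gene passed in any fit that left out 1 library.

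The second comparison asked what the fusion protein did without radiation. Type I interferon genes rose together, and the lectin genes Cd209a and Cd209d fell, Cd209d in only 1 of the 6 fits that left out a library. Slfn4, an interferon-induced schlafen gene of myeloid cells (ENSMUSG00000000204.16, chromosome 11, 83175186 to 83190216), averaged 12730 ± 10850 normalized counts with the fusion protein and 63.1 ± 38.8 without (SD, n = 3). Ifi44, another interferon-induced gene (chromosome 3, 151730922 to 151749960), averaged 3416 ± 2310 and 159.3 ± 45.7, and Siglec1, the sialic acid lectin CD169 of macrophages (chromosome 2, 131069220 to 131086765), 1509 ± 851.5 and 77.1 ± 38.9. Cd209a, a relative of human DC-SIGN that marks monocyte-related and type 2 dendritic cells (ENSMUSG00000031494.7, chromosome 8, 3743397 to 3748984), averaged 39.7 ± 21.3 with the fusion protein and 869.4 ± 161.9 without.

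Of the 38 type I interferon list members, 31 rose and 0 fell over all genes, and all 38 were higher and passed when adjusted over the list alone. Ifi27l2a rose by 3.33 ± 0.25 on the log2 scale, Ifit3b by 4.13 ± 0.34, Oas3, which makes the second messenger that activates RNase L, by 3.34 ± 0.28, and Ifit3 by 3.83 ± 0.37 (SE; limma adjusted p 0.00038, 0.00038, 0.00038 and 0.001). These 4 were called in each fit that left out 1 library. The list median was 2.84, with a camera adjusted p of 3.7e-85 and 0.0352 with an estimated correlation. With the block and an estimated correlation the call was lost (0.138). The number of members called was 19 without fusion protein library 1, 20 without untreated library 2, and 22 to 31 without another library. It was 14 when only the 6 compared libraries were fitted. Of 30 interferon gamma members, 2 rose: Gbp4, a guanylate-binding protein (1.37 ± 0.20, limma adjusted p = 0.0109), and Irgm2, an immunity-related GTPase (1.70 ± 0.28, 0.0191). Without fusion protein library 1 these were 0.0553 and 0.102, and Gbp4 was kept in 5 of the 6 fits and Irgm2 in 3. When adjusted over the list alone 13 passed, and with the block 16 passed over all genes. The median was 1.41, with a camera adjusted p of 6.9e-15 and an adjusted p of 0.336 with an estimated correlation. Of 21 MHC class I presentation members, 1 rose, the non-classical H2-T22 (1.85 ± 0.29, limma adjusted p = 0.0148, 0.0713 without fusion protein library 1, kept in 3 of the 6 fits), 10 passed when adjusted over the list alone and 9 passed with the block. The median was 0.71 (camera adjusted p = 5.1e-12, adjusted p = 0.43 with an estimated correlation).

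All 36 cell cycle members were higher, by a median of 0.87. Over all genes 1 passed, the mitotic motor Cenpe (1.35 ± 0.26, limma adjusted p = 0.0444), which was lost in 5 of the 6 fits that left out 1 library, with 0.186 without fusion protein library 1. When adjusted over the list alone 30 passed, among them Cdk1, the mitotic kinase, at 1.51 ± 0.33, and with the block 17 passed over all genes. Camera gave an adjusted p of 3e-26, and 0.334 with an estimated correlation. Of 20 cytotoxic and NK cell members, 19 were higher (median 0.66) and 1 rose, the granule protease Gzma, which averaged 23210 ± 9657 counts against 5908 ± 889 (SD, n = 3). Its log2 fold change was 1.89 ± 0.31 (limma adjusted p = 0.0165, 0.0776 without untreated library 2, kept in 2 of the 6 fits). Gzmb, granzyme B, averaged 50220 ± 48080 and 3752 ± 3511, with a limma adjusted p of 0.108, and 9.6e-05 with the block. When adjusted over the list alone 5 members passed, and with the block 6 passed over all genes. The camera adjusted p was 3.7e-09, and 0.336 with an estimated correlation.

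Few single markers of conventional dendritic cells passed with the fusion protein, and camera called their lists lower only at its preset correlation. In fusion protein library 3, where melanoma transcripts were high and B cell transcripts low, the mean of the pan conventional list was 8.56, against 10.40 and 10.56 in libraries 1 and 2, and that of MHC class II 10.10, against 11.47 and 11.90. Of 18 cDC1 members 1 fell, Gcsam, a lymphocyte signalling adaptor (−2.14 ± 0.41, limma adjusted p = 0.0384), which was lost in each of the 6 fits. When adjusted over the list alone 7 passed, all lower, and with the block 7 fell and 1 rose over all genes. Xcr1, the chemokine receptor that defines cDC1 (chromosome 9, 123852315 to 123862029), averaged 126.9 ± 85.1 counts with the fusion protein and 555 ± 94.5 without, at a log2 of −2.48 ± 0.53 (limma adjusted p = 0.0685, and 0.0061 with the block). Cadm1 had a log2 fold change of −1.47 ± 0.33 (limma adjusted p = 0.0884). The list median was −1.03 (camera adjusted p = 5.9e-06, kept in each fit that left out 1 library, and adjusted p = 0.292 with an estimated correlation). Of 14 pan conventional dendritic cell members 1 fell, Kit, the stem cell factor receptor (−1.60 ± 0.30, limma adjusted p = 0.0362, 0.143 without fusion protein library 3, kept in 2 of the 6 fits). Flt3, the growth factor receptor on which dendritic cells depend, averaged 583.6 ± 304 and 2440 ± 1084, with a limma adjusted p of 0.0586, and 0.00108 with the block. When adjusted over the list alone 2 passed, and with the block 3 fell. The median was −0.98 (camera adjusted p = 0.0001, adjusted p = 0.523 with an estimated correlation). Without fusion protein library 3 the median was −0.17 and the camera adjusted p was 0.154. Of 17 cDC2 members 1 fell, Cd209a, and 2 passed when adjusted over the list alone, Cd209a and the lectin Mgl2 (−3.49 ± 0.98). The cDC2 median was −0.42 (camera adjusted p = 0.00385, 0.386 with an estimated correlation), and −0.12 without untreated library 1 (camera 0.0994), with the call also lost without fusion protein library 3.

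Of 15 MHC class II members 0 passed over all genes and 4 passed lower when adjusted over the list alone, among them Cd74, the invariant chain (−1.11 ± 0.34), and H2-Ab1 (−1.15 ± 0.36). The median was −0.95 (camera adjusted p = 0.0004, 0.523 with an estimated correlation), and −0.24 without fusion protein library 3 (camera 0.128), with the call also lost without untreated library 1. In the plasmacytoid list (median −0.70, camera adjusted p = 0.0013) 0 of 16 members passed over all genes. The transcription factor Tcf4 (−0.87) and the lectin Siglech (−1.61) were lower and the interferon-induced Bst2 (1.47) higher when adjusted over the list alone. The call was lost without untreated library 2 (0.0685) or untreated library 3, and the adjusted p was 0.523 with an estimated correlation. Of 16 monocyte members 1 rose, Ms4a4c, a membrane protein of inflammatory monocytes (2.07 ± 0.34, limma adjusted p = 0.0182, 0.0828 without untreated library 2, kept in 2 of the 6 fits), 4 passed when adjusted over the list alone, and 6 rose and 1 fell with the block. Its median was 0.59 (camera adjusted p = 0.00242, 0.523 with an estimated correlation), and 0.17 without untreated library 2 (camera 0.0981), with the call also lost without fusion protein library 1. The IL-4 and STAT6 list (median −0.75, camera adjusted p = 0.0112) had 1 of 16 members that fell, Cd209d, and 2 that passed when adjusted over the list alone. Its adjusted p was 0.513 with an estimated correlation, and 0.144 by camera without untreated library 3, with the call also lost without fusion protein library 1.

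The mature regulatory dendritic cell list had a median of −0.27 with 12 of 34 members higher and 0 passing over all genes or over the list alone (camera adjusted p = 0.485, adjusted p = 0.886 with an estimated correlation). With the block, the chemokine Ccl5 passed (1.05, limma adjusted p = 0.0312). Camera also called cytokines (median 0.70, adjusted p = 0.0171, and 0.19 and 0.506 without fusion protein library 3, lost without untreated library 2 too), cholesterol synthesis (−0.26, 0.0281, and 0.12 and 0.668 without untreated library 3, lost without fusion protein libraries 1 or 2 too) and neutrophil (0.75, 0.0399, and −0.07 and 0.979 without fusion protein library 1, lost without fusion protein library 3 or untreated libraries 2 or 3 too). With an estimated correlation adjusted p was 0.835, 0.868 and 0.868. In lists with no camera call, single members still rose: the complement factor Cfb (3.45 ± 0.58, limma adjusted p = 0.0197) of the lysosome and complement list, and Ltbp1, which binds latent TGF-beta (3.62 ± 0.72, 0.0481), of the TGF-beta list. Each was kept in 2 of the 6 fits, with 0.107 and 0.217 without fusion protein library 1. Medians of the lists without a call were 0.13 for lysosome and complement, −0.26 for TGF-beta, −0.04 for costimulation, −0.16 for coinhibition, −0.11 for NF-kB, 0.21 for p53, −0.09 for lipid handling, 0.46 for macrophage, 0.28 for T cell, −0.50 for regulatory T cell, 0.26 for B and plasma cell, 0.50 for melanoma, 0.67 for fibroblast and endothelium, −0.52 for erythroid, −0.09 for dissociation stress and −0.30 for mitochondrial transcripts (camera adjusted p 0.0596 to 0.969). Chemokines (0.46, adjusted p = 0.0955), innate sensing (0.27, 0.0509), glycolysis and hypoxia (0.34, 0.36) and mast cell and basophil (1.10, 0.0508) were called only with the block, at 0.0134, 0.00737, 0.0361 and 0.0283. With the block and an estimated correlation these were 0.526, 0.477, 0.815 and 0.526.

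Ccl22 averaged 129.2 ± 139.7 with the fusion protein and 399.2 ± 268 without (SD, n = 3), at a log2 fold change of −2.22 ± 1.44 (limma adjusted p = 0.821). The other fixed genes had log2 fold changes of −1.21 (Ccl17), −0.36 (Ccr7), −0.34 (Fscn1), 0.36 (Cd274), −0.77 (Il12b), −0.69 (Cxcl9), 2.65 (Cxcl10), −0.81 (Foxp3) and −0.55 (Itgax). Their limma adjusted p values lay between 0.704 and 0.998.

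Limma called 136 genes with the fusion protein, 107 higher and 29 lower, of which 132 had a log2 fold change of at least 1. With the block it called 602 (416 higher), all 136 among them. The largest rises were those of Slfn4 (7.04 ± 0.92, limma adjusted p = 0.00501), Fabp3, a fatty acid binding protein (6.36 ± 0.91, 0.00877), Adgrb1, a receptor for phosphatidylserine on dying cells (5.66 ± 0.93, 0.018), Sh2d1b2, an adaptor of SLAM family receptors (4.68 ± 0.57, 0.00332), Spon1, the matrix protein F-spondin (4.39 ± 0.81, 0.033), Siglec1 (4.28 ± 0.53, 0.00332), Ifi44 (4.25 ± 0.45, 0.0016) and Pde7b, a cyclic AMP phosphodiesterase (4.21 ± 0.75, 0.0269). The largest falls were those of Cd209a (−4.57 ± 0.41, 0.000653), Cd209d (−4.45 ± 0.78, 0.0251), Ngfr, the p75 neurotrophin receptor (−3.73 ± 0.73, 0.0462), Rgs7bp (−3.67 ± 0.46, 0.00332), Gprc5c, an orphan receptor (−3.11 ± 0.38, 0.00332), Cgnl1, a junction protein (−3.08 ± 0.50, 0.0176), Rnf150 (−2.74 ± 0.52, 0.0378) and Hrh1, the histamine H1 receptor (−2.70 ± 0.46, 0.023). Of these 16, the calls of Slfn4, Sh2d1b2, Siglec1, Ifi44, Cd209a, Rgs7bp and Gprc5c were kept in each of the 6 fits that left out 1 library. The number of genes called fell to 46 without fusion protein library 1, 64 without untreated library 2, 72 without fusion protein library 3 and 77 without untreated library 3. The highest adjusted p was 0.0596 for Fabp3, 0.0963 for Adgrb1, 0.164 for Spon1, 0.138 for Pde7b, 0.204 for Ngfr and 0.0836 for Cgnl1, each without fusion protein library 1. It was 0.112 for Cd209d without untreated library 2, 0.0818 for Hrh1 without untreated library 3 and 0.131 for Rnf150 without fusion protein library 3. Of the 6 fits, Fabp3 was kept in 5, Adgrb1 in 3, Spon1, Pde7b, Ngfr and Cgnl1 in 2, Cd209d and Hrh1 in 1 and Rnf150 in 0.

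The third comparison asked what the fusion protein added to 20 Gy. Of the 31 type I interferon members that rose with the fusion protein alone, 30 rose here as well, and Cd209a fell. Ifit3b, an antiviral protein (chromosome 19, 34607970 to 34613401), averaged 3975 ± 867.4 normalized counts in the combined group and 186.2 ± 83.9 after 20 Gy (SD, n = 3). Cd209a averaged 35.2 ± 10.8 and 1114 ± 82.3. Sct, the secretin hormone, which plasmacytoid dendritic cells also transcribe (chromosome 7, 141278330 to 141279133), averaged 151.3 ± 28.9 and 3.77 ± 4.79, and Cadm1 (chromosome 9, 47530173 to 47857637) averaged 185.6 ± 9.98 and 969.3 ± 176.

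Of the 38 type I interferon members 34 rose and 0 fell, and all 38 passed when adjusted over the list alone. Ifit3b rose by 4.47 ± 0.34, Ifit3 by 4.46 ± 0.37, Usp18, a brake on interferon receptor signalling, by 3.65 ± 0.32, and Oas3 by 3.19 ± 0.28 (SE; limma adjusted p 0.000317, 0.000355, 0.00046 and 0.00046). The median was 2.81 (camera adjusted p = 1.3e-84, adjusted p = 0.036 with an estimated correlation). The members called were 20 or 21 without 20 Gy library 1, 20 Gy library 2, combined library 1 or combined library 3. Of 30 interferon gamma members 6 rose, including Gbp4 (1.95 ± 0.20, limma adjusted p = 0.000894), Tgtp2 (2.71 ± 0.42, 0.0091), Irgm2 (1.81 ± 0.28, 0.00962) and Nlrc5, the activator of MHC class I genes (1.22 ± 0.20, 0.013), and 18 passed when adjusted over the list alone. The median was 1.84 (camera adjusted p = 8e-20, adjusted p = 0.23 with an estimated correlation). Of these 4 Gbp4 was kept in each fit that left out 1 library. Tgtp2, Irgm2 and Nlrc5 were lost without combined library 3 (0.0619, 0.0667 and 0.0874), combined library 1 or 20 Gy library 2, and Irgm2 and Nlrc5 without 20 Gy library 1 too. Of 21 MHC class I members 4 rose, H2-T22 (2.45 ± 0.29, limma adjusted p = 0.00184), H2-Q7 (1.74 ± 0.25, 0.0061), Nlrc5 and H2-Q4 (1.39 ± 0.27, 0.0348), and 14 passed when adjusted over the list alone. The median was 0.80 (camera adjusted p = 2.1e-16, adjusted p = 0.287 with an estimated correlation). H2-Q4 was lost in 5 of the 6 fits.

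All 20 cytotoxic and NK cell members were higher (median 1.01). Over all genes Gzma rose (18580 ± 1427 counts against 4251 ± 1285), by 2.17 ± 0.31 (limma adjusted p = 0.00495), and 9 passed when adjusted over the list alone. Gzmb had a log2 fold change of 4.08 ± 0.88 (limma adjusted p = 0.0581). Camera gave an adjusted p of 1.2e-13, and 0.23 with an estimated correlation. Of 18 cDC1 members 1 fell, Cadm1 (−2.36 ± 0.33, limma adjusted p = 0.00495, kept in each fit that left out 1 library), and 8 passed lower when adjusted over the list alone, among them Xcr1 (−2.24 ± 0.53) and Gcsam (−1.85 ± 0.41). The median was −0.88 (camera adjusted p = 1.4e-05, adjusted p = 0.23 with an estimated correlation). Cd209a was the cDC2 member that fell (list median −0.59, camera adjusted p = 0.00285, adjusted p = 0.287 with an estimated correlation), and 2 cDC2 members passed when adjusted over the list alone. Kit was the pan conventional member that fell (−1.71 ± 0.30, limma adjusted p = 0.0195, 0.124 without combined library 3, kept in 2 of the 6 fits). That list had 1 higher and 3 lower members when adjusted over the list alone, a median of −0.61 and a camera adjusted p of 0.0235, with adjusted p = 0.785 with an estimated correlation. Its call was lost without combined library 3 (0.104) or 20 Gy library 1.

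Of 16 monocyte members Ms4a4c (2.27 ± 0.34, limma adjusted p = 0.00717) and Ly6c2, the surface antigen of inflammatory monocytes (3.53 ± 0.55, 0.00931), rose. Without combined library 3 these were 0.0543 and 0.0619, and they were kept in 3 and 2 of the 6 fits. The matrix protein Fn1 was at −4.20 ± 0.92 (limma adjusted p = 0.0616), 3 higher and 1 lower members passed when adjusted over the list alone, and the median was 0.25 (camera adjusted p = 0.0995). The IL-4 and STAT6 list, markers of alternatively activated macrophages, had a median of −1.33 with 0 of 16 members passing over all genes and 4 passing lower when adjusted over the list alone: Ccl24 (−5.14), Cd209d (−3.23), Mgl2 (−4.01) and the mannose receptor Mrc1 (−3.81). Its camera adjusted p was 0.000255, 0.0966 without 20 Gy library 3, and 0.273 with an estimated correlation. Tlr9, the endosomal receptor for unmethylated DNA, rose by 1.51 ± 0.22 (limma adjusted p = 0.0061, kept in each fit that left out 1 library) in the innate sensing list, where 4 of 25 passed when adjusted over the list alone (median 0.28, camera adjusted p = 0.00599, adjusted p = 0.613 with an estimated correlation). Camera called the cell cycle list (34 of 36 higher, median 0.41, adjusted p = 9.3e-08), the erythroid list (all 8 lower, −3.50, 0.000354), cholesterol synthesis (all 20 lower, −0.43, 0.00362), the macrophage list (−0.91, 0.012) and MHC class II (−0.71, 0.012), with 0 members passing in each. With an estimated correlation their adjusted p was 0.649, 0.613, 0.785, 0.785 and 0.785. Without 20 Gy library 3 the median and camera adjusted p were −0.05 and 0.808 for cholesterol synthesis, −0.74 and 0.252 for macrophage, also lost without combined library 2, and −0.73 and 0.0858 for MHC class II. In lists with no camera call, Cma1, a mast cell chymase (2.09 ± 0.38, limma adjusted p = 0.0228, and 0.12 without combined library 1), Lgals9, galectin 9 (1.92 ± 0.36, 0.0282, and 0.141 without combined library 3), Cfb (3.65 ± 0.58, 0.0102, and 0.0776 without combined library 3) and Ltbp1 (3.62 ± 0.72, 0.0381) rose. Of the 6 fits, Cfb was kept in 3, Cma1 in 2, Lgals9 in 1 and Ltbp1 in 0.

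**Figure D4:**
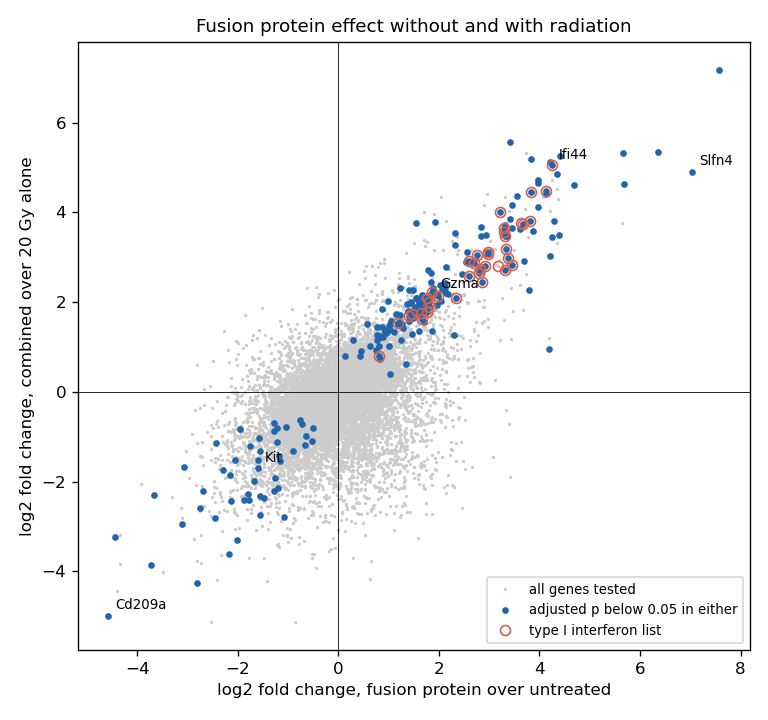
Log2 fold change of the fusion protein without radiation (x axis, fusion protein over untreated) and with it (y axis, combined over 20 Gy) for each tested gene, with genes at an adjusted p under 0.05 in either comparison in blue and the 38 type I interferon members circled in red. The red circles lie at the upper right, with list medians of 2.84 and 2.81.

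Ccl22 averaged 111.6 ± 86.5 counts in the combined group and 1377 ± 2058 after 20 Gy (SD, n = 3), at a log2 fold change of −2.66 ± 1.44 (limma adjusted p = 0.682). The other fixed genes were at −3.42 (Ccl17), 0.01 (Ccr7), −0.42 (Fscn1), 0.73 (Cd274), −0.56 (Il12b), −0.35 (Cxcl9), 3.16 (Cxcl10), −2.03 (Foxp3) and −0.35 (Itgax), with limma adjusted p values of 0.483 to 1. The mature regulatory dendritic cell list had a median of −0.20 (camera adjusted p = 0.822), with Ccl5 passing when adjusted over the list alone (1.19 ± 0.27).

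Limma called 188 genes, 154 higher and 34 lower, of which 179 had a log2 fold change of at least 1. The largest rises were those of Sct (5.57 ± 0.70, limma adjusted p = 0.00234), Fabp3 (5.34 ± 0.91, 0.0165), Adgrb1 (5.33 ± 0.93, 0.0187), Prm1, a protamine of sperm chromatin (5.25 ± 1.02, 0.0347), Ifi44 (5.05 ± 0.45, 0.00046), Slfn4 (4.90 ± 0.92, 0.0291), Sh2d1b2 (4.61 ± 0.57, 0.0023) and Ifit3b. The largest falls were those of Cd209a (−4.99 ± 0.41, 0.000355), Ngfr (−3.87 ± 0.73, 0.031), P3h2, a collagen prolyl hydroxylase (−3.61 ± 0.73, 0.0411), Trf, transferrin (−3.31 ± 0.51, 0.00863), Gprc5c (−2.95 ± 0.38, 0.00286), Fgfr1, a fibroblast growth factor receptor (−2.80 ± 0.34, 0.00191), Stxbp6 (−2.79 ± 0.52, 0.0276) and Rnf150 (−2.59 ± 0.52, 0.0405). Of these 16, Sct, Ifi44, Sh2d1b2, Ifit3b, Cd209a, Gprc5c and Fgfr1 were kept in each of the 6 fits that left out 1 library. The number called was 76 without combined library 3, 79 without 20 Gy library 2, 82 without combined library 1 and 86 without 20 Gy library 1. The highest adjusted p was 0.115 for Fabp3, 0.124 for Adgrb1, 0.203 for Prm1 and 0.157 for Slfn4 without combined library 3, and 0.199 for P3h2, 0.0544 for Trf and 0.198 for Rnf150 without 20 Gy library 1. Of the 6 fits, Trf was kept in 5, Adgrb1 in 3, Fabp3 and Slfn4 in 2, Prm1, P3h2 and Rnf150 in 1 and Ngfr and Stxbp6 in 0.

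The fourth comparison set the combined treatment against no treatment. Interferon-induced genes rose and Cd209a fell. The neutrophil and monocyte lists were higher by camera as after 20 Gy, with adjusted p = 0.442 and 0.41 with an estimated correlation. Slfn4 averaged 27600 ± 14330 counts against 63.1 ± 38.8, Ifi27l2a 6708 ± 1504 against 580.1 ± 9.07, and the inflammatory monocyte gene Ly6c2 12710 ± 3177 against 1944 ± 1152 (SD, n = 3).

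Of the 38 type I interferon members 37 rose and all 38 passed when adjusted over the list alone (median 3.41, camera adjusted p = 2e-75). The adjusted p was 0.0516 with an estimated correlation. The members called were 28 without combined library 1 and 27 without combined library 3. Ifit3b was at 4.77 ± 0.34, Ifi27l2a at 3.50 ± 0.25, Oas3 at 3.79 ± 0.28 and Ifit3 at 4.43 ± 0.37, each kept in the 6 fits that left out 1 library. Of 30 interferon gamma members 6 rose, among them Irgm2 (2.21 ± 0.28, limma adjusted p = 0.00229), Gbp4 (1.48 ± 0.20, 0.00392) and Gbp6 (3.19 ± 0.59, 0.0228), 20 passed when adjusted over the list alone and 24 rose with the block (median 1.75, camera adjusted p = 3e-17, adjusted p = 0.41 with an estimated correlation). Irgm2 and Gbp4 were kept in each fit that left out 1 library, and Gbp6 was lost without combined library 3 (0.126), each other combined library or untreated library 2. Of 21 MHC class I members H2-T22 (2.04 ± 0.29) and Nlrc5 (0.97 ± 0.20) rose, 14 passed when adjusted over the list alone and 13 rose with the block (median 0.85, camera adjusted p = 7.3e-10, adjusted p = 0.58 with an estimated correlation). The call of Nlrc5 was lost in 5 of the 6 fits, with 0.203 without combined library 3. All 36 cell cycle members were higher (median 0.70, camera adjusted p = 3.6e-13, adjusted p = 0.58 with an estimated correlation). Of these the spindle protein Tpx2 rose (1.58 ± 0.34, limma adjusted p = 0.0497), a call lost in each of the 6 fits, while 12 passed when adjusted over the list alone and 13 rose with the block.

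All 17 neutrophil members were higher (median 3.24), with 0 passing over all genes, 11 when adjusted over the list alone and 10 with the block (camera adjusted p = 9.3e-10, adjusted p = 0.442 with an estimated correlation). Of 16 monocyte members Ms4a4c (2.94 ± 0.34, limma adjusted p = 0.00124), Ly6c2 (2.93 ± 0.55, 0.024), Hp (3.26 ± 0.65, 0.0316) and Plac8 (1.97 ± 0.40, 0.0343) rose, and 6 passed when adjusted over the list alone. Without combined library 3 the last 3 had adjusted p values of 0.132, 0.166 and 0.174, and they were kept in 3, 2 and 2 of the 6 fits. The monocyte median was 1.44 (camera adjusted p = 1e-05, adjusted p = 0.41 with an estimated correlation). The innate sensing list had a median of 1.16 (camera adjusted p = 1.4e-05, adjusted p = 0.41 with an estimated correlation). Its members Ifi204, an interferon-induced DNA sensor (4.30 ± 0.72, limma adjusted p = 0.0127), and Tlr9 (1.26 ± 0.22, 0.0171) rose, 7 passed when adjusted over the list alone and 11 rose with the block. Both genes were lost without combined library 3 (0.0815 and 0.104), combined library 1 or untreated library 2, and Tlr9 without untreated library 3 too. In the lysosome and complement list (median 0.43, camera adjusted p = 0.00016, adjusted p = 0.607 with an estimated correlation) Cfb (4.26 ± 0.58, limma adjusted p = 0.00356) and C3 (1.55 ± 0.29, 0.0248) rose and 8 rose with the block. C3 was lost without combined library 3 (0.146), combined library 1 or untreated libraries 1 or 2. In the cytokine list (median 1.02, camera adjusted p = 0.00101, adjusted p = 0.619 with an estimated correlation) 0 passed over all genes and 3 when adjusted over the list alone, Il27 (4.52), Il18 (2.39) and Il15 (1.68), with 8 rising under the block. The calls of these 5 lists were kept in each fit that left out 1 library.

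T cell members were lower in 23 of 23 (median −0.58, camera adjusted p = 0.00516, and 0.656 without untreated library 2, lost without combined library 1 too), and regulatory T cell members in 11 of 12 (−1.09, 0.0214, and 0.218 without untreated library 2, lost without untreated library 3 or combined library 1 too). No member of either passed, and with the block 3 of each fell. The adjusted p of these lists was 0.715 and 0.678 with an estimated correlation. Other camera calls were also lost in at least 1 fit that left out a library, those of chemokines (1.47, 0.0106, and 0.187 without untreated library 1, lost without untreated library 2 or combined library 3 too; 7 members rose with the block), cytotoxic and NK cell (0.27, 0.0106, and 0.126 without untreated library 1; Gzma rose by 1.66 ± 0.31, a call lost in 5 of the 6 fits, with 0.12 without combined library 3), macrophage (1.12, 0.0451, and 0.858 without untreated library 2, lost without combined library 3 too), fibroblast and endothelium (1.60, 0.0167, and 0.127 without combined library 3, lost without untreated library 1 too), cholesterol synthesis (−0.33, 0.0161, and 0.956 without untreated library 3, lost without combined library 2 too) and IL-4 and STAT6 (−0.88, 0.0161, and 0.136 without untreated library 3). The adjusted p was 0.678 for chemokines, cytotoxic and macrophage lists, 0.607 for fibroblast and endothelium, 0.715 for cholesterol synthesis and 0.586 for IL-4 and STAT6 with an estimated correlation. In the fit of highest adjusted p the median was 1.32 for chemokines, 0.31 for cytotoxic and NK cell, 0.33 for macrophage, 0.70 for fibroblast and endothelium, 0.08 for cholesterol synthesis, −0.83 for IL-4 and STAT6, −0.16 for T cell and −0.68 for regulatory T cell. The cDC1 list had a median of −0.17 (adjusted p = 0.284), cDC2 of −0.49 (0.0535) and pan conventional DC of −0.38 (0.13), in which Kit fell by 1.71 (limma adjusted p = 0.0168, 0.104 without combined library 3, kept in 4 of the 6 fits). Melanoma (1.14, adjusted p = 0.284), mast cell and basophil (1.14, 0.0553) and coinhibition (0.23, 0.102) lists were called only with the block, at 0.0365, 0.0287 and 0.0365, and had adjusted p values of 0.658, 0.468 and 0.461 with the block and an estimated correlation.

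Ccl22 was at −2.10 ± 1.44 on the log2 scale (limma adjusted p = 0.623). The other fixed genes were at −1.70 (Ccl17), −0.47 (Ccr7), −0.38 (Fscn1), 1.11 (Cd274), 0.43 (Il12b), 0.02 (Cxcl9), 3.72 (Cxcl10), −1.70 (Foxp3) and −0.29 (Itgax), with limma adjusted p values of 0.302 to 0.996. With the block 3 of them passed: Cxcl10 (0.00554), Cd274 (0.0229) and Foxp3 (0.0346). The mature regulatory dendritic cell list had a median of 0.02 (camera adjusted p = 0.855). With the block 4 of its 34 members rose, among them Cd40 (1.21, limma adjusted p = 0.0168) and Ebi3 (1.12, 0.027).

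Limma called 256 genes, 221 higher and 35 lower, of which 243 had a log2 fold change of at least 1, and with the block 1413 (958 higher), all 256 among them. The largest rises were those of Slfn4 (8.72 ± 0.92, limma adjusted p = 0.000718), Fabp3 (7.17 ± 0.91, 0.00222), Adgrb1 (6.68 ± 0.93, 0.00408), the complement gene C4b (6.57 ± 1.22, 0.0232), Prm1 (0.0178), Spon1 (5.58 ± 0.81, 0.00508), Aplnr, the apelin receptor (5.39 ± 0.70, 0.00262), and Pde7b (5.26 ± 0.75, 0.00482). Prm1 averaged 64.5 ± 46.7 counts and was at 0 in all untreated libraries. The largest falls were those of Cd209a (−4.62 ± 0.41, 0.000329), Ngfr (−4.05 ± 0.73, 0.0198), Cd209d (−3.88 ± 0.78, 0.0336), Trf (−2.71 ± 0.51, 0.0238), Slc25a23, a mitochondrial carrier (−2.38 ± 0.41, 0.0148), Gprc5c (−2.31 ± 0.38, 0.0113), Fgfr1 (−2.29 ± 0.34, 0.00562) and Grm8, a glutamate receptor (−2.24 ± 0.46, 0.0353). Of these 16, Slfn4, Fabp3, Adgrb1, Spon1, Aplnr, Pde7b, Cd209a and Fgfr1 were kept in each of the 6 fits that left out 1 library. The number called was 93 without combined library 3, 98 without combined library 1 and 129 without untreated library 2. The highest adjusted p was 0.126 for C4b and Prm1, 0.177 for Cd209d, 0.0953 for Slc25a23 and 0.171 for Grm8 without combined library 3, and 0.11 for Ngfr, 0.111 for Trf and 0.0708 for Gprc5c without combined library 1. Of the 6 fits, Gprc5c was kept in 5, Slc25a23 in 3, C4b, Prm1 and Ngfr in 2 and Cd209d, Trf and Grm8 in 1.

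The fifth comparison asked what 20 Gy added to the fusion protein. No gene passed. The neutrophil list was called higher and the T cell list lower by camera, as with 20 Gy alone, while the cell cycle list was called lower here (−0.17) and higher with 20 Gy alone (0.35). None of these calls held with an estimated correlation (adjusted p 0.351 to 0.719), and those of the cell cycle list were lost without fusion protein library 3 (0.486, median 0.03) and without 20 Gy library 3 (0.418). Fmnl2, a formin that shapes the actin cytoskeleton, averaged 1610 ± 349 counts in the combined group and 805 ± 207 with the fusion protein (SD, n = 3). Pglyrp1, a peptidoglycan-binding protein, averaged 338 ± 40.1 and 552 ± 63.2, and the Max-binding repressor Mxd4 767 ± 111 and 1298 ± 280. These were among the 12 genes of smallest p, all at a limma adjusted p of 1, with Col24a1 (3.63), AC102496.1, Muc3 (2.71), Ucp1 (3.27) and Clec2f (2.36) higher and Cdan1 (−0.61), Dab2ip (−0.80), Fam210b (−0.96) and Adamts14 (−0.66) lower. AC102496.1, a long non-coding RNA, averaged 5.8 ± 2.99 counts and was at 0 in all fusion protein libraries. The 10 fixed genes also had a limma adjusted p of 1, with log2 fold changes of 0.12 (Ccl22), −0.48 (Ccl17), −0.10 (Ccr7), −0.04 (Fscn1), 0.74 (Cd274), 1.20 (Il12b), 0.72 (Cxcl9), 1.07 (Cxcl10), −0.89 (Foxp3) and 0.26 (Itgax).

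No list member passed in this comparison, over all genes or over its list alone. All 38 type I interferon members were higher, by a median of 0.56 (camera adjusted p = 2.9e-11), as were all 17 neutrophil members (2.23, 1.6e-10) and 15 of 18 cDC1 members (0.84, 1.2e-06), while all 23 T cell members were lower (−0.85, 1.5e-08). Lysosome and complement (0.54, 1.2e-06), innate sensing (0.62, 1.4e-05) and lipid handling (0.64, 0.0014) were higher by camera too. With an estimated correlation the adjusted p was 0.54 for the interferon, T cell and lysosome lists, 0.448 for the neutrophil, innate sensing and lipid lists and 0.423 for cDC1. These 7 calls were kept in each fit that left out 1 library. The other calls were lost in at least 1 fit that left out a library. Without fusion protein library 3, MHC class II (0.51, 0.00021) had a median of −0.01 (adjusted p = 0.861), cell cycle (−0.17, 0.0011) of 0.03 (0.486) and pan conventional DC (0.46, 0.00405, lost without combined library 1 too) of −0.12 (0.486). Medians of cytotoxic and NK cell (−0.30, 0.00018, and 0.291 without fusion protein library 1), monocyte (0.67, 0.00112, and 0.0535 without fusion protein library 2), erythroid (1.95, 0.00456, and 0.385 without fusion protein library 2) and mitochondrial transcripts (0.45, 0.00112, and 0.271 without combined library 2) kept their sign. Interferon gamma (0.47, 0.00112, and 0.0786), coinhibition (0.51, 0.00902, and 0.144), macrophage (0.61, 0.0322, and 0.311) and fibroblast and endothelium (1.11, 0.0281, and 0.465) were lost without combined library 3, the first also without fusion protein library 2, coinhibition and fibroblast also without fusion protein library 1, and macrophage also without either. The regulatory T cell list (all 12 lower, −0.69, 0.0149) had an adjusted p of 0.456 without combined library 1, and was lost without fusion protein library 2 or 3 too. These 12 lists had adjusted p values of 0.54 to 0.684 with an estimated correlation. With the block camera also called chemokines (0.88, adjusted p = 0.109, and 0.00296 with the block), cytokines (0.50, 0.0679 and 0.00405), costimulation (0.68, 0.078 and 0.00804), NF-kB (0.20, 0.22 and 0.00978) and dissociation stress (−0.14, 0.078 and 0.0348). With both the block and an estimated correlation these were 0.407, 0.407, 0.334, 0.667 and 0.419. Limma called 0 genes, against 534 at an unadjusted p under 0.05. The test of edgeR called 0 (493 unadjusted) and DESeq2 called 0 (713 unadjusted), and no fit that left out 1 library called a gene.

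**Figure D5:**
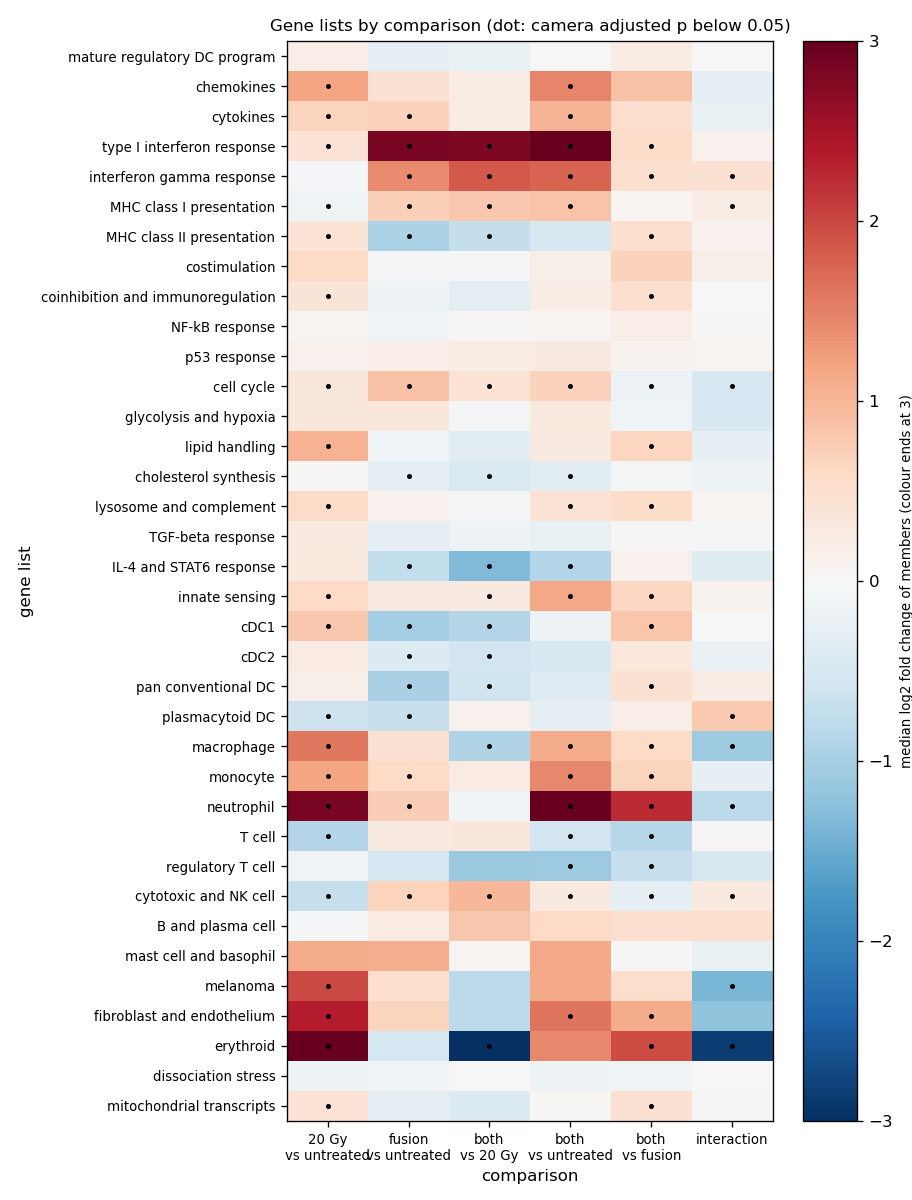
Median log2 fold change of the members of each gene list (y axis) in each comparison (x axis), in colour from blue (lower) through white to red (higher), with the colour scale ending at −3 and 3. The type I interferon list is red where the fusion protein is added (2.84, 2.81 and 3.41), and the neutrophil list where 20 Gy is set against no treatment or added (2.86 and 2.23).

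The sixth comparison asked whether 20 Gy and the fusion protein acted differently together than apart. As an interaction, limma called 0 genes, against 188 at an unadjusted p under 0.05, while edgeR called 0 (221 unadjusted) and DESeq2 called 1 (309 unadjusted), Xlr3b. Of the 12 genes of smallest p, the positive terms included those of Tlr9 (0.93 ± 0.31), Hsf5 (3.40 ± 1.31), Tcf4 (0.78 ± 0.30), Tmem86a (0.86 ± 0.34) and Cstad (1.51 ± 0.59), and the negative ones those of Xlr3b (−5.04 ± 0.91), Upp2 (−5.32 ± 1.17), Col10a1 (−4.85 ± 1.14), Srgap1 (−4.41 ± 1.06), Col4a4 (−4.33 ± 1.05) and Klf15 (−4.80 ± 1.36), all at a limma adjusted p of 1. The terms of the fixed genes lay between −2.20 for Ccl17 and 0.52 for Cxcl10, with −0.44 for Ccl22, and had a limma adjusted p of 1. The type I interferon list had an interaction median of 0.12 (camera adjusted p = 0.303).

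The fusion protein comparisons with and without radiation share no library. Across 18274 genes their log2 fold changes had a Pearson r of 0.506 and a Spearman rho of 0.452, and 68.3% had the same sign. Correlations are across genes, which are not independent replicates. Of the genes called, 94 were higher in both (0.9 for independent lists) and 15 lower in both (0.05), and 0 went opposite ways. All 136 genes called without radiation had the same sign with it, and the median difference, with radiation minus without, was 0.173 on the log2 scale. Leaving out 1 library gave an r of 0.387 to 0.565, and a filter at 50 gave 0.769. The radiation comparisons with and without the fusion protein, which also share no library, had an r of 0.47, a rho of 0.466 and the same sign in 68.5% of genes, with an r of 0.211 to 0.586 when 1 library was left out and 0.64 with a filter at 50. What 20 Gy did and what the fusion protein added to it share the 20 Gy libraries. Their r was −0.392, against −0.499 in 20 simulations of unchanged groups, and their covariance −0.26 against −0.233, a difference of −0.027. The r was −0.57 to −0.224 when 1 library was left out, the latter without combined library 2, and −0.208 with a filter at 50.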

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

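The interaction tests were planned before the data were examined, while the tests used below to weigh explanations were chosen after the results were seen. For genomic DNA the covariate was chosen after seeing the data, and its prediction was written before its own result. These lists were singled out because the effect of the fusion protein differed between irradiated and unirradiated samples by camera on the interaction term. The median interaction was 0.45 for the interferon gamma response (camera adjusted p = 0.0103), 0.22 for MHC class I presentation (0.0205), 0.78 for plasmacytoid DC (2.2e-10) and 0.29 for cytotoxic and NK cell (0.0495). It was −0.50 for cell cycle (2.2e-10), −1.07 for macrophage (6.2e-05), −0.79 for neutrophil (0.0328), −1.37 for melanoma (0.0229) and −2.84 for erythroid (0.00063). With an estimated correlation no list was called, and the lowest adjusted p was 0.819, for plasmacytoid DC. By gene, DESeq2 singled out Xlr3b, at a log2 interaction of −6.20 ± 1.28 (DESeq2 adjusted p = 0.0253), with a limma adjusted p of 1. Its counts were 1.5, 1.2 and 0 in untreated, 16.9, 5.1 and 7.7 in fusion protein, 29, 30 and 24.9 in 20 Gy and 5.4, 3.9 and 2.6 in combined libraries.

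The first pattern was the high Ccl22 in 20 Gy library 3, a log2 of 4.46 above libraries 1 and 2. For a larger share of mature dendritic cells, a first test on Ccr7 and Fscn1 (higher by 3.66 and 3.37) was set aside, as these genes had been picked for the same pattern, and a second on the other 31 mature regulatory dendritic cell members gave a median of 1.42 (SD 1.52), which cannot tell. The mean of that list was higher by 1.48 there, those of chemokines by 2.86, glycolysis and hypoxia by 2.47 and melanoma by 5.51, and that of pan conventional DC was at −0.63. Transcripts carried over from melanoma cells could not be told apart from this: scaled by Tyrp1, the Ccl22 excess was 1.11 of that foreseen in untreated library 3, 0.24 in combined library 3 and −0.06 in fusion protein library 3, where the fusion protein itself may change Ccl22. In 20 Gy libraries 1 and 2 Ccl22 had 105 and 274 counts, against 122.8 to 657.9 untreated. With this spread, a 20 Gy response in every sample or in some stays open.

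The second pattern was the fall of Cd209a with the fusion protein, beside cDC1 and pan conventional lists that camera called lower with it alone (adjusted p = 0.292 and 0.523 with an estimated correlation) and when added to 20 Gy (0.23 and 0.785), but not in the combined group against untreated (medians −0.17 and −0.38). For a lower cDC2 share, the other 16 members had a median of −0.38 (SD 0.97, from −3.49 for Mgl2 to 0.80) against −4.57 for Cd209a. With 5 of 17 in other lists, this cannot tell. For a lower share of conventional dendritic cells, regulatory T cells had the lowest median of 8 other cell type lists, −0.50 (SD of members 0.72) without radiation and −1.10 (0.99) with it. Their library means differed by −0.38 and −0.95, within an SD between libraries of 1.37 and 1.33, with library 1 lowest in each group. With this condition, added after the first result, the test could not tell. The biological explanation is a change within the cells through the fusion protein, and both may act together.

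The third pattern was the higher neutrophil and erythroid lists after 20 Gy. For blood in the samples, list means centred by group had a Pearson r of 0.983 and a Spearman rho of 0.958 over 12 libraries. Without the 2 farthest from the median r was 0.958. The exact permutation p of each was 0.00463 over 1296 orders within groups, which ignore that samples of the same number correlate. It was 0.167, the smallest possible, over 6 orders of whole replicate sets. With 1 relation and no control list, this cannot tell. Against blood alone, the T cell list was lower after 20 Gy by 0.88, the CD45 gate would remove red cells, and where the fusion protein was added to 20 Gy the erythroid list had a median of −3.50 and the neutrophil list of −0.08. Genomic DNA as the whole cause is argued against, since with the receptor gene level as a covariate the median of the 25 members was 2.66 (SD 1.5), and 3.6 without (SD 1.33), while entry of neutrophils into irradiated tumours was not tested and stays open, as the fusion protein may itself change neutrophils.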

How the results depend on the processing

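The settings below were fixed before the data were examined, except the fits without the 4 libraries numbered 3 and with the receptor gene level as a covariate, which were chosen after seeing the data. No result reversed. Of 14443 values for single genes and lists, genes kept their side of the threshold in 11529, were weaker in 349 and stronger in 321, and lists in 1886, 255 and 103. Of the genes that kept their side, 212 values changed sign while passing in neither fit. No filter, a filter at 50, other pseudocounts, TMM, upper-quartile scaling and edgeR kept each total within a factor of 1.5. The lower genes went from 35 to 17 for combined against untreated with no filter, and from 34 to 22 for combined against 20 Gy in edgeR.

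With DESeq2 on whole reads the genes called were 45 for 20 Gy against untreated, 464 for the fusion protein against untreated, 550 for combined against 20 Gy, 755 for combined against untreated and 1 for the interaction. With the replicate block they were 70, 602, 834 and 1413 in the first 4. With sample weights, whose fit stopped before convergence, they were 220, 836 and 1146 in the last 3 of these. With only the compared groups they were 18 for the fusion protein, 149 for combined against untreated and 189 for combined against 20 Gy. Combined against untreated gave 168 without the libraries numbered 3 and 107 with the receptor covariate. The cause of these changes was not tested.

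Leaving out 1 library gave 46 (without fusion protein library 1) to 179 (without fusion protein library 2) genes for the fusion protein, 76 (without combined library 3) to 202 (without 20 Gy library 3) for combined against 20 Gy, and 93 (without combined library 3) to 278 (without untreated library 1) for combined against untreated. The correlation of the fusion protein effects without and with radiation was 0.769 with a filter at 50, where genes of few counts are left out. Of named genes, 100 of 622 gene and comparison pairs passed, against 172 with DESeq2, 169 with sample weights and 219 with the block, and 64 to 102 without 1 library. List calls were 95, against 2 with an estimated correlation and 3 by fry.

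With the fusion protein alone, 31 type I interferon members rose, against 26 in edgeR, 14 with only the compared groups, 38 with the block and 26 with the covariate. Cd209a, Ifi27l2a, Ifi44, Ifit3, Ifit3b and Oas3 were called there in all 19 alternatives. Slfn4 and Rgs7bp (highest adjusted p 0.102 and 0.118) were lost with only the compared groups and without the libraries numbered 3, and Siglec1 (0.0527), Sh2d1b2 (0.0596) and Gprc5c (0.0714) with only the compared groups, by limma adjusted p. Depth and 3 samples per group limit single genes: few changes of a log2 of 1 were recovered in simulation.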

Other observations

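The genes in this part were chosen after their values were seen, and the reading of the splits of the samples was written after their results were seen. The complement genes C4b and Cfb had higher values with the fusion protein, while the lysosome and complement list was not called without radiation (median 0.13). C4b, an early complement component, averaged 15.3 ± 14.2 normalized counts in untreated, 445 ± 201 in fusion protein, 112 ± 150 in 20 Gy and 829 ± 341 in combined libraries (SD, n = 3). Cfb, the protease of the alternative pathway, averaged 9.51 ± 6.28, 103.4 ± 27.9, 15.4 ± 10.1 and 187.5 ± 67.7 in the same order. Fgfr1 averaged 394 ± 128, 68.6 ± 7.27, 543 ± 78.9 and 80.8 ± 30.9, and Kit 1995 ± 853, 633.9 ± 154, 1880 ± 141 and 584.9 ± 135.

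Splitting the same 6 libraries in every other way into groups of 3 tested how many genes the structure of the samples gives. With 10 splits the share cannot fall under 0.05. The count was matched or passed in 1 of 10 splits, the real one, for the fusion protein against untreated (136 genes, 2 in the highest other), combined against 20 Gy (188 and 0) and combined against untreated (256 and 0). Where the real count was 0, every split had to match it, so these shares carry no information: 10 of 10 for 20 Gy against untreated (0 genes, 1014 in the highest other) and combined against the fusion protein (0 and 0). The split with 1014 set untreated library 1 and 20 Gy libraries 1 and 2 against the rest, which points to structure of the samples other than the dose, and the splits that parted all 3 pairs of numbers gave 0. For the interaction the real count was also 0 and the 100 of 100 splits carry none either, with 1079 genes in the highest other.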
